A study of Mus musculus with 48 samples.

How the data were processed

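Total RNA of sorted retinal cells in 48 mouse samples was sequenced on an Illumina HiSeq from TruSeq RNA v2 libraries, per the labels' protocols and the series' design text. The submitters' processing notes name FastQC 0.11.2, TopHat, Cufflinks 2.0.1.3 and the build mm10, with no roles or options. The gene annotation is not given in the sources used here. The authors deposited 1 table of FPKM values (fragments scaled by transcript length and sequencing depth), with 23997 rows named by gene symbol and 1 column per sample. The lowest value was 0.1 in 35.7% of the cells, and the 9 highest values all had 0.1 after the whole number. So 0.1 had been added to every value and stands for 0. The libraries had already been scaled to one another, since their upper quartiles lay between 14.1 and 15.5 FPKM and their median ratio factors between 0.985 and 1.024. Column totals ran from 439267 to 849106, of which 6.24 to 53.52% fell on 1211 rows of small RNAs, whose FPKM are uncertain because the transcripts are shorter than usual fragments. In 27 rows a spreadsheet had turned the symbol into a date, and these are not named.

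Groups were taken from the genotype and stage labels, and titles only numbered the libraries. Titles carry a number shared by several libraries, whose meaning is not stated, and a suffix, and 4 libraries carry several suffixes. The replicate numbers used here follow the order of deposition and pair no samples. No 2 columns were identical.

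Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and figures were drawn with matplotlib 3.10.9. FPKM are not counts, so no count model was used. Rows with a value of at least 1 in at least 3 libraries were kept (13564, of them 50 of small RNAs). One linear model over the 7 groups, with a trended and robust estimate of the spread, gave 14 contrasts, 11 between groups and 3 interactions of genotype with stage. P-values were adjusted within each contrast by the Benjamini-Hochberg method, and genes under 0.05 count as changed. A change on the log2(FPKM + 1) scale understates the fold change of weakly expressed genes. The median change over all genes of a contrast lay no further from 0 than -0.0473. Before the data were examined, 28 gene lists of pathways and cell types were fixed, of which 3 to 32 genes each were tested. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated for each list (own-correlation adjusted p). Besides the counts over all genes, members were counted with p-values adjusted over the list alone.

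Named genes follow a rule fixed beforehand. For each comparison these are Rb1, Rbl1 and Pten, up to 4 most changed members of each list with a mean of at least 1 in the higher group, the 6 largest rises and falls without overlap between libraries and a mean of at least 5, and 11 genes chosen in advance, of which Pou4f2, Tfap2b and Glul went unreported. For the interactions 4 rises and 4 falls were taken by adjusted p. Pdk1 in TKO_D0 against DKO_D0 was named after its values were seen. Coordinates are those of GENCODE vM21 on mm10, in which 22627 rows matched 1 gene by symbol.

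The procedure was tested on simulated data with 200 of 13564 genes changed by each fold. For Rb_D7 against WT_D7 it found 43, 74 and 93.5% of genes changed 1.3, 1.5 and 2-fold, with 4.75% false among its calls. For TKO_D7 against DKO_D7 it found 69, 88.5 and 98%, with 5.55% false. In both it found all 20 shifted lists, and 1 and 0 of 200 unshifted. Rates in correlated data can differ. Alternatives were a pseudocount of 0.1, a filter at 5 FPKM or none, quantile or median ratio scaling, the compared groups alone, library weights, title number as a block or averaged, and single libraries or those of several suffixes left out.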

Results

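RNA was sequenced from mouse retinal cells sorted for green fluorescent protein, which marked cells where Cre recombinase, driven from the CHX promoter, had acted. The 47 libraries with consistent labels formed 7 groups by genotype and by a stage labelled D0 or D7. Wild type cells were sampled at D0 (WT_D0, n = 7) and D7 (WT_D7, n = 5), and cells labelled deltaRb, without the retinoblastoma gene Rb1, at D7 alone (Rb_D7, n = 3). Cells that also lacked Rbl1, which encodes the related pocket protein p107, were sampled at D0 (DKO_D0, n = 7) and D7 (DKO_D7, n = 7). Cells that lacked Rb1, Rbl1 and the phosphatase gene Pten were sampled at D0 (TKO_D0, n = 10) and D7 (TKO_D7, n = 8). The labels class the wild type and Rb_D7 libraries as normal, the DKO and TKO_D0 libraries as pre-tumorigenic and the TKO_D7 libraries as tumor. One further library carried D0 in its title and D7 in its stage label and entered no comparison. FPKM were available for 23997 rows, of which 13564 were tested. Read counts were not given, so the depth behind each value is unknown. Gene lists were tested at a preset and an estimated correlation (own-correlation adjusted p). Largest changes are those without overlap between libraries and with a mean of at least 5 FPKM. Changes are log2 differences of group means ± the standard error, and group levels are mean FPKM ± SD. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples. Among compared groups only Rb_D7 and WT_D7, and DKO_D0 and DKO_D7, shared a title number. So batch and group cannot be told apart in all other comparisons, at D0, at D7 and between stages. Libraries of a title number are named by it. In the first principal component, which held 42.99% of the variance, the WT_D7 and Rb_D7 libraries lay on the negative side of all the other libraries, and in the second, with 13.52%, the DKO_D7, Rb_D7 and TKO_D7 libraries lay above all D0 libraries.

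**Figure D1:**
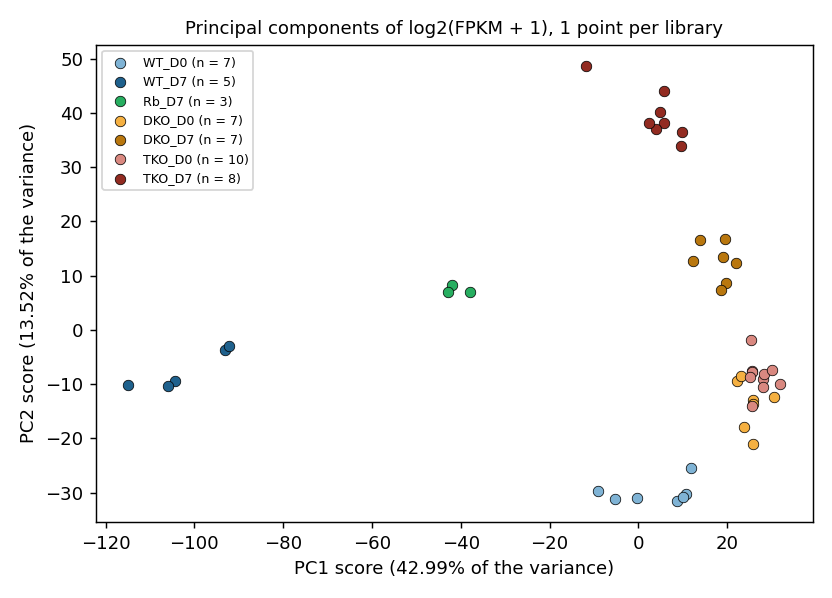
First and second principal component scores of log2(FPKM + 1), 1 point per library, coloured by group. WT_D7 libraries lay between -114.86 and -92.28 on the first component and TKO_D7 libraries between 33.85 and 48.6 on the second.

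The deleted genes were examined first. Rbl1 measured between 0.301 and 0.664 FPKM in the 7 DKO_D0 libraries, 0.544 to 0.963 in DKO_D7, 0.429 to 1.16 in TKO_D0 and 0.533 to 1.48 in TKO_D7. In WT_D0 it measured 20.01, 18.3, 35.9, 0.487, 42.9, 41.8 and 43.7 FPKM in libraries 1 to 7. Replicate 4, the library labelled wild type with 0.487, therefore lay within the range of the mutants. Rbl1 was 5.5 to 12.9 FPKM in WT_D7 and 32.1 to 35.9 in Rb_D7, which keeps the gene. The fall from WT_D0 was 3.80 ± 0.37 in DKO_D0 (adjusted p = 1.68e-10, limma) and 3.61 ± 0.34 in TKO_D0 (adjusted p = 2.23e-11). Rb1 was not lower in the deleted groups. It measured 31.6 to 38.9 FPKM in WT_D0 and 29.9 to 40.6 in WT_D7, against 57.7 to 68.5 in Rb_D7, 40.8 to 55.6 in DKO_D0, 57.3 to 64.6 in DKO_D7, 36.1 to 54.3 in TKO_D0 and 61 to 86.8 in TKO_D7. Pten measured 28.7 to 33.9 FPKM in DKO_D0 and 24.6 to 39.2 in TKO_D0, and 26.2 to 34.4 in DKO_D7 and 24.4 to 28.8 in TKO_D7. Its difference between TKO and DKO was -0.03 ± 0.07 at D0 (adjusted p = 0.774) and -0.12 ± 0.07 at D7 (adjusted p = 0.15). At D0 it was -0.218 without title number 1084380, TKO_D0 6 to 10 (adjusted p = 0.0057), and 0.152 with it alone (0.045), so the value near 0 averages opposite differences. A value for a whole gene does not check the loss of part of its exons, so the Rb1 and Pten genotypes rest on the labels.

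**Figure D2:**
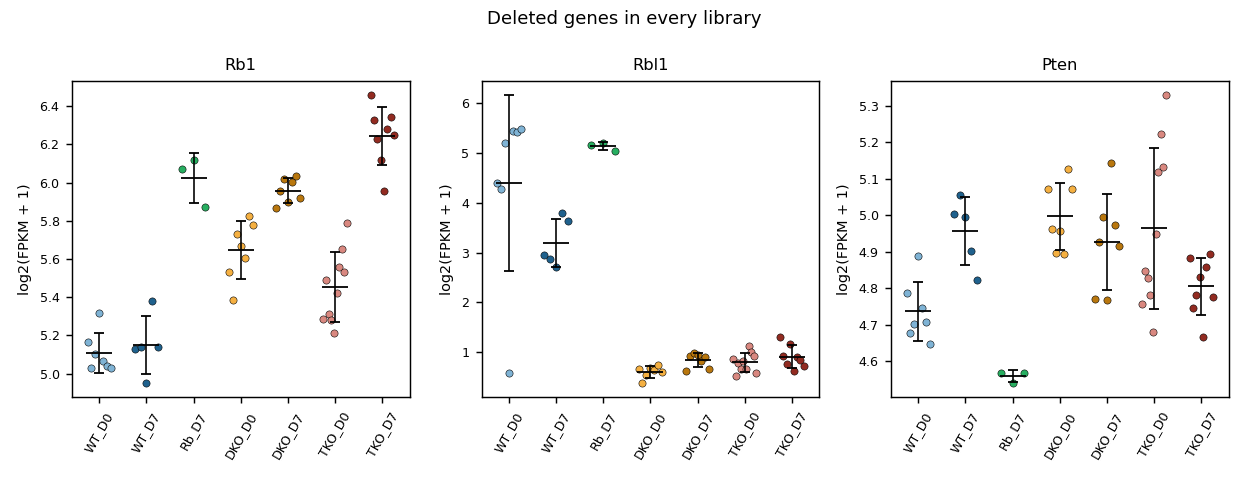
log2(FPKM + 1) of Rb1, Rbl1 and Pten by group, with 1 point per library and bars for the mean and SD. The WT_D0 point at the bottom of the Rbl1 panel is the library with 0.487 FPKM.

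Loss of Rb1 and Rbl1 was compared with the wild type at D0. Photoreceptor genes were lower in DKO_D0, and genes of amino acid stress, glycolysis and cell division were higher. Crx, a transcription factor of photoreceptor precursors, fell by 3.06 ± 0.18 on the log2 scale (59.2 ± 26.7 FPKM in WT_D0, n = 7, and 5.67 ± 0.807 in DKO_D0, n = 7; adjusted p = 3.6e-17), and Nrl, which sets rod fate, fell by 2.68 ± 0.33. The cone G protein subunit genes Gngt2 and Gnb3 fell by 4.53 ± 0.36 and 2.95 ± 0.23, and Rbp3 and Fabp7 by 3.57 ± 0.30 and 3.44 ± 0.28. Of the cone genes 7 of 8 fell (adjusted p = 6.18e-09, own-correlation adjusted p = 0.0233), and of the rod genes 15 of 23, Pdc and Nr2e3 among them at -3.16 ± 0.38 and -3.15 ± 0.38 (adjusted p = 1.06e-09, own-correlation adjusted p = 0.359). Nrl lay between 12.4 and 36.2 FPKM in WT_D0 libraries 1 to 4 and between 6.55 and 6.94 in libraries 5 to 7, a difference between title numbers, and between 0.53 and 1.88 in DKO_D0. Targets of ATF4, the transcription factor of the amino acid response, rose in 15 of 19 (adjusted p = 8.11e-10, own-correlation adjusted p = 0.143), with Stc2 up by 1.94 ± 0.22, Asns by 1.80 ± 0.25 and Slc7a5 by 1.26 ± 0.17. Glycolysis genes rose in 16 of 20 (1 fell, adjusted p = 5.32e-09, own-correlation adjusted p = 0.288), led by Pdk1 (1.90 ± 0.20), Aldoa (1.22 ± 0.23) and Hk2 (1.17 ± 0.15). Among the hypoxia and angiogenesis genes 8 of 15 (1 fell) rose (adjusted p = 0.000727, own-correlation adjusted p = 0.359), with Bnip3 at 2.06 ± 0.26 and Vegfa at 0.89 ± 0.15. Both rises were largely in title number 1047823, DKO_D0 3 to 7, where the glycolysis and hypoxia genes averaged 6.147 to 6.475 and 3.658 to 3.977 (log2). They averaged 5.293 and 3.222 in DKO_D0 1 and 5.537 and 3.414 in DKO_D0 2, against 5.252 to 5.395 and 3.173 to 3.347 in WT_D0. S phase genes rose in 20 of 32 (adjusted p = 9.03e-09, own-correlation adjusted p = 0.602), including Ccne2 (0.96 ± 0.17), Cdc6 (0.89 ± 0.18) and Mcm10 (0.73 ± 0.12). Mitotic genes rose in 18 of 25 (adjusted p = 1.66e-05, own-correlation adjusted p = 0.723), including Ttk (0.84 ± 0.13) and Mki67 (0.59 ± 0.16). Of the E2F and pocket protein genes 7 of 11 rose (adjusted p = 0.00247, own-correlation adjusted p = 0.359), E2f2 by 0.99 ± 0.16. Of the p53 target and apoptosis genes 10 of 21 rose (adjusted p = 5.63e-05, own-correlation adjusted p = 0.143), Trp73 by 2.28 ± 0.22 and Sesn2 by 1.12 ± 0.20. The CDK inhibitor gene Cdkn1a rose by 1.01 ± 0.23 and Ccnd1, which encodes cyclin D1, fell by 0.87 ± 0.14. Vgll3 (2.00 ± 0.13) was among the largest rises. In all, 4806 of 13564 genes changed, 2335 higher and 2471 lower, of which 48 and 138 changed at least 2-fold. Adjusted over the list alone, 7 cone, 16 rod, 16 ATF4, 17 glycolysis, 10 hypoxia, 23 S phase, 20 mitotic, 8 E2F family, 11 p53 and 6 sterol genes passed. Sterol and fatty acid genes passed as a list in the other direction, with 6 of 25 lower (adjusted p = 0.029, own-correlation adjusted p = 0.768), but not without WT_D0 5, 6 or 7 or DKO_D0 3, 4, 5 or 6 (adjusted p = 0.0754 to 0.156) or with the compared groups alone or 1 mean per title number (0.0564 to 0.516). With each title number averaged first 515 genes passed, and Aldoa, Bnip3, Ccnd1, Ccne2, Cdc6, Cdkn1a, E2f2, Mcm10, Mki67, Sesn2, Ttk and Vegfa did not (adjusted p = 0.06 to 0.391). Without title number 1032030, left out after the data were seen, 2883 genes passed, of which 2519 were among the 4806. The mitotic list (adjusted p = 0.494), the E2F family list (0.0698) and Mki67 (0.103) then did not pass, Nr2e3 fell by 2.02 and Ttk rose by 0.56. WT_D0 4 was kept, and without it 4889 genes passed.

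With Pten deleted as well, TKO_D0 differed from WT_D0 in 7099 genes, 3363 higher and 3736 lower (90 and 192 at least 2-fold). Photoreceptor genes were lower here too, glycolysis and amino acid genes were higher, and targets of FOXO, the transcription factors that AKT keeps out of the nucleus, were lower. Crx fell by 3.08 ± 0.17 (adjusted p = 3.33e-18), Nrl by 2.84 ± 0.30, Gngt2 by 4.08 ± 0.33 and Fabp7 by 4.10 ± 0.26. Of the cone genes 7 of 8 fell (adjusted p = 4.51e-06, own-correlation adjusted p = 0.0771) and of the rod genes 15 of 23 (adjusted p = 1.39e-06, own-correlation adjusted p = 0.602). Of the FOXO targets 10 of 17 (1 rose) fell (adjusted p = 0.000263, own-correlation adjusted p = 0.0217), Txnip by 1.78 ± 0.13 (53.5 ± 14.8 FPKM in WT_D0, n = 7, and 14.7 ± 3.35 in TKO_D0, n = 10), Pik3ip1 by 1.23 ± 0.12 and Irs2 by 0.83 ± 0.12. Glycolysis genes rose in 19 of 20 (1 fell, adjusted p = 1.41e-12, own-correlation adjusted p = 0.0995), with Aldoa at 2.08 ± 0.21, Pdk1 at 2.05 ± 0.18 and Slc2a3 at 1.81 ± 0.17. ATF4 targets rose in 18 of 19 (adjusted p = 5.64e-10, own-correlation adjusted p = 0.0995), with Stc2 at 2.40 ± 0.20 and Asns at 2.19 ± 0.23. Hypoxia genes rose in 10 of 15 (1 fell, adjusted p = 0.000419, own-correlation adjusted p = 0.351), with Bnip3 at 2.43 ± 0.24, Egln3 at 1.37 ± 0.14 and Adm at 1.23 ± 0.24. S phase genes rose in 17 of 32 and mitotic genes in 18 of 25 (adjusted p = 0.000236 and 0.000261, both own-correlation adjusted p = 0.819), with Mki67 at 0.79 ± 0.15. Of the p53 target and apoptosis genes 15 of 21 (1 fell) rose (adjusted p = 0.0012, own-correlation adjusted p = 0.251), Tnfrsf10b by 1.29 ± 0.12. Sterol genes rose in 13 of 25 (2 fell, adjusted p = 0.0144, own-correlation adjusted p = 0.825), Scd1 by 1.3 ± 0.11. E2F family genes rose in 5 of 11 (adjusted p = 0.0352, own-correlation adjusted p = 0.669). Neurogenic genes fell in 9 of 18 (2 rose, adjusted p = 0.0308, own-correlation adjusted p = 0.624), Neurod4 by 1.44 ± 0.16 and Neurod1 by 1.15 ± 0.13. Mt1 (2.73 ± 0.35), AA465934 (4.75 ± 0.27), Anxa2 (2.61 ± 0.21) and Crhbp (2.53 ± 0.29) were among the largest rises. Cdkn1c rose by 1.15 ± 0.15, Cdkn1a by 0.97 ± 0.21, while Ccnd1 fell by 0.92 ± 0.13. Members past the threshold adjusted over the list alone were 7 cone, 15 rod, 11 FOXO, 20 glycolysis, 18 ATF4, 11 hypoxia, 17 S phase, 19 mitotic, 17 p53, 16 sterol, 5 E2F family and 11 neurogenic genes. Without 1032030, 4912 genes passed and the mitotic list did not (adjusted p = 0.5), with Mt1 at 4.18. With each title number averaged first Mki67 did not pass (adjusted p = 0.122). The sterol list no longer passed without 1032030, with 1084380 alone or library weights or after quantile normalization (adjusted p = 0.07 to 0.844), nor the E2F family list without WT_D0 1 or 3 (adjusted p = 0.0593 to 0.0653) or without 1084380 or 1032030, with 1084380 alone, a pseudocount of 0.1, library weights or 1 mean per title number or after quantile normalization (0.0572 to 0.352), nor the neurogenic list with 1084380 alone (adjusted p = 0.131), where Adm was at 0.73.

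TKO_D0 was compared with DKO_D0, the pre-tumorigenic groups whose labels differ in Pten. Genes of sterol and fatty acid synthesis and of glycolysis were higher in TKO_D0 and FOXO targets were lower. Sterol genes rose in 18 of 25 (adjusted p = 4.14e-12, own-correlation adjusted p = 0.348), with Scd1 up by 1.56 ± 0.11 (0.907 ± 0.467 FPKM in DKO_D0, n = 7, and 4.58 ± 1.09 in TKO_D0, n = 10; adjusted p = 2.11e-14), Msmo1 by 0.67 ± 0.14 and Ldlr by 0.67 ± 0.18. Of the FOXO targets 11 of 17 fell (adjusted p = 5.56e-08, own-correlation adjusted p = 0.000102), among them Txnip (-1.05 ± 0.13), Irs2 (-0.85 ± 0.12), Pik3ip1 (-0.58 ± 0.12) and Foxo4 (-0.54 ± 0.08). Glycolysis genes rose in 12 of 20 (adjusted p = 5.48e-07, own-correlation adjusted p = 0.676), with Gapdh at 0.86 ± 0.09, Aldoa at 0.86 ± 0.21 and Eno1 at 0.70 ± 0.11. The glycolysis call rested on the 2 DKO_D0 libraries of title number 1032037. Their Pdk1 was low (9.52 and 13 FPKM against 28.3 to 37.3 in the others). Without them the list gave adjusted p = 0.104 and Eno1 rose by 0.45. With title number 1084380 alone for TKO_D0 the list gave adjusted p = 0.0593. Immediate early genes fell in 7 of 18 (2 rose, adjusted p = 0.0375, own-correlation adjusted p = 0.996), Egr1 by 1.11 ± 0.26 and Junb by 0.98 ± 0.23. Neurogenic genes fell in 7 of 18 (adjusted p = 0.0407, own-correlation adjusted p = 0.996), Neurod4 by 0.66 ± 0.16. Hes5 (-0.70 ± 0.16), Trp73 (-1.04 ± 0.20) and Mycn (-0.44 ± 0.10) fell as well, and Tnfrsf10b (0.63 ± 0.12), Hspa1a (0.76 ± 0.10) and Sfrp2 (0.55 ± 0.13) rose. The largest rises were AA465934 (4.44 ± 0.27), Tagap1 (2.22 ± 0.08) and Gpr137b-ps (1.92 ± 0.12). The like-named Tagap and Gpr137b fell (-1.654 and -0.922), for a cause not tested. The largest falls included Sh3gl3 (-1.34 ± 0.14), Luzp2 (-1.21 ± 0.10) and Ndrg2 (-1.10 ± 0.13). Of the S phase and mitotic genes 3 of 32 and 1 of 25 fell (camera adjusted p = 0.293 and 0.976). The total was 2988 genes, 1432 higher and 1556 lower, with 23 and 26 at least 2-fold. By p-values adjusted over the list alone, 19 sterol, 12 FOXO, 12 glycolysis, 11 immediate early and 8 neurogenic genes passed. The immediate early list no longer passed without DKO_D0 1 or 3 or TKO_D0 3 or 4 (adjusted p = 0.0746 to 0.105) or without 1084380, 1032037 or the libraries of several suffixes or with 1084380 alone (0.0612 to 0.153), nor the neurogenic list without DKO_D0 3 or 6 or TKO_D0 2 or 4 (adjusted p = 0.0712 to 0.153) or with 1084380 alone, the filter at 5 FPKM or 1 mean per title number or after quantile normalization (0.0761 to 0.571). With 1084380 alone 4988 genes passed, and without them 2343, of which 1393 were among the 2988. Without them Junb, Ldlr and Sfrp2 did not pass (adjusted p = 0.0847, 0.0563 and 0.0951), and with them alone Aldoa and Neurod4 did not (0.0634 and 0.0587). Without 1032037 or with the compared groups alone Aldoa did not pass (0.084 and 0.0748), with library weights it was at 0.52, and without 1032037 Ldlr was at 1.05. With title number as a random block 661 genes passed, and the calls of Hes5, Junb, Ldlr, Msmo1, Neurod4 and Sfrp2 ended (adjusted p = 0.059 to 0.228). With each title number averaged first 134 genes passed, and the calls of these genes and of Aldoa, Egr1, Mycn and Trp73 ended (adjusted p = 0.131 to 0.739).

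At D7 the loss of Rb1 alone was compared with the wild type. Every measured cell cycle gene of both lists was higher in Rb_D7, and genes of bipolar cells and rods were lower. S phase genes rose in 32 of 32 and mitotic genes in 25 of 25 (adjusted p = 7.06e-29 and 2.78e-25, both own-correlation adjusted p = 0.0975). Rrm2 rose by 3.27 ± 0.27, Mcm6 by 3.19 ± 0.28, Top2a by 3.08 ± 0.24 and Mki67 by 3.00 ± 0.23 (12.9 ± 7.01 FPKM in WT_D7, n = 5, and 100 ± 19.1 in Rb_D7, n = 3; adjusted p = 1.69e-15). Bipolar genes fell in 19 of 19 (adjusted p = 1.82e-28, own-correlation adjusted p = 0.00015), with the ON bipolar receptor and channel genes Grm6 and Trpm1 at -4.87 ± 0.10 and -4.59 ± 0.29, Pcp2 at -4.27 ± 0.28 and Scgn at -4.20 ± 0.11, and Vsx2, a transcription factor of progenitors and bipolar cells, fell by 2.34 ± 0.13. Rod genes fell in 14 of 23 (adjusted p = 4.16e-07, own-correlation adjusted p = 0.431), rhodopsin (Rho) by 3.89 ± 0.21 and recoverin (Rcvrn) by 2.97 ± 0.17. Of the E2F and pocket protein genes 8 of 11 rose and 1 fell (adjusted p = 1.16e-05, own-correlation adjusted p = 0.105), E2f7 rising by 2.93 ± 0.21 and E2f1 by 2.04 ± 0.18. Rbl1, which is not on this list, rose by 1.95 ± 0.51. Neurogenic genes rose in 12 of 18 (adjusted p = 1.16e-05, own-correlation adjusted p = 0.0975), Insm1 by 1.87 ± 0.18 and Dll4 by 1.69 ± 0.19. Progenitor genes rose in 11 of 18 (1 fell, adjusted p = 0.0129, own-correlation adjusted p = 0.515), with Foxn4 at 3.25 ± 0.25, though the progenitor list gave adjusted p = 0.0838 without Rb_D7 replicate 3. Interferon response genes rose in 13 of 15 (adjusted p = 0.000764, own-correlation adjusted p = 0.243), Usp18 by 1.40 ± 0.21 and B2m by 1.33 ± 0.21. Of the CDK inhibitor and D cyclin genes 6 of 9 rose (adjusted p = 0.0129, own-correlation adjusted p = 0.157), Cdkn1a by 2.43 ± 0.31, Cdkn2c by 1.99 ± 0.16 and Cdkn2a by 1.67 ± 0.23, and Trp73 rose by 2.88 ± 0.29. Of the genes altered in human retinoblastoma 4 of 7 rose (adjusted p = 0.0129, own-correlation adjusted p = 0.157), Kif14 by 2.49 ± 0.18 and Dek by 1.80 ± 0.14. Immediate early genes rose in 13 of 18 (adjusted p = 0.0129, own-correlation adjusted p = 0.684). Genes of the p53 target and apoptosis list rose in 10 of 21 (adjusted p = 0.0414, own-correlation adjusted p = 0.503). Glycolysis genes fell in 10 of 20 (2 rose, adjusted p = 0.0129, own-correlation adjusted p = 0.684). The immediate early list no longer passed without Rb_D7 3 (adjusted p = 0.12), nor the p53 target list without Rb_D7 1 or 2 or WT_D7 2 (adjusted p = 0.0606 to 0.0616). Rb_D7 replicate 3 stood apart, with Nrl at 15.2 FPKM against 96.1 and 100 in the others and Mki67 at 78.1 against 109 and 113. In WT_D7, Mki67 was 5.03 to 9.57 FPKM in libraries 1 to 3 and 19.99 and 20.7 in libraries 4 and 5. In all 6444 genes changed, 3326 higher and 3118 lower, 758 and 684 of them at least 2-fold. When adjusted over the list alone, 32 S phase, 25 mitotic, 19 bipolar, 14 rod, 10 E2F family, 13 neurogenic, 13 progenitor, 13 interferon, 6 CDK, 5 retinoblastoma, 13 immediate early, 12 p53 and 14 glycolysis genes passed. Within title number 1047745, which both groups share, 6230 genes passed (3 libraries against 3), 5986 of them among the 6444.

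Loss of both Rb1 and Rbl1 was compared with the wild type at D7. Bipolar, rod and cone genes were lower in DKO_D7, and cell cycle and progenitor genes were higher. Mki67 rose by 4.25 ± 0.18 (12.9 ± 7.01 FPKM in WT_D7, n = 5, and 237 ± 32.4 in DKO_D7, n = 7; adjusted p = 3.66e-25), E2f8 by 4.30 ± 0.15, Top2a by 4.11 ± 0.20 and Uhrf1 by 4.02 ± 0.21. S phase genes rose in 32 of 32 and mitotic genes in 25 of 25 (adjusted p = 2.06e-18 and 2.99e-18, both own-correlation adjusted p = 0.194). Bipolar genes fell in 18 of 19 (adjusted p = 3.17e-17, own-correlation adjusted p = 0.00669), with Isl1 at -7.38 ± 0.22, Grm6 at -6.97 ± 0.08 and Pcp2 at -6.84 ± 0.22, and Vsx2 fell by 2.65 ± 0.11. Rod genes fell in 23 of 23 (adjusted p = 1.28e-11, own-correlation adjusted p = 0.194), Pdc by 5.21 ± 0.41, Sag by 4.63 ± 0.22 and Rho by 4.49 ± 0.17. Cone genes fell in 8 of 8 (adjusted p = 0.00391, own-correlation adjusted p = 0.194), Gnb3 by 6.42 ± 0.25 and Gngt2 by 5.33 ± 0.39. Progenitor genes rose in 16 of 18 (1 fell, adjusted p = 0.000129, own-correlation adjusted p = 0.194), Foxn4 by 3.67 ± 0.20, Sfrp2 by 2.11 ± 0.15 and the Notch effector gene Hes5 by 1.94 ± 0.19. Neurogenic genes rose in 10 of 18 (4 fell, adjusted p = 0.0268, own-correlation adjusted p = 0.433), Sox11 by 3.03 ± 0.10, though not with the compared groups alone or after quantile normalization (adjusted p = 0.0649 to 0.0691). Penk rose by 3.19 ± 0.16. Immediate early genes rose in 15 of 18 (adjusted p = 0.00614, own-correlation adjusted p = 0.569), Egr1 by 2.04 ± 0.31 and Klf4 by 2.05 ± 0.28. ATF4 targets rose in 13 of 19 (2 fell, adjusted p = 0.00757, own-correlation adjusted p = 0.494), Stc2 by 2.63 ± 0.24 and Phgdh by 2.59 ± 0.18. The lens list fell in 5 of 6 (adjusted p = 0.0291, own-correlation adjusted p = 0.194), with Cryab and Cryba1 at -3.86 ± 0.23 and -2.15 ± 0.24, but not without the filter, with a pseudocount of 0.1 or after quantile normalization (adjusted p = 0.0526 to 0.157). Müller glia genes fell in 12 of 17 and rose in 4 (adjusted p = 0.0694), with Abca8a at -3.40 ± 0.12 and Clu at -2.65 ± 0.27. The pan-neuronal tubulin gene Tubb3 fell by 3.40 ± 0.22, while the amacrine factor genes Prdm13 and Ptf1a rose by 2.78 ± 0.37 and 2.30 ± 0.29. E2F family genes rose in 10 of 11 (1 fell) and CDK inhibitor and D cyclin genes in 7 of 9 (1 fell, adjusted p = 4.68e-05 and 0.0173, both own-correlation adjusted p = 0.194), Cdkn1a by 2.67 ± 0.25. Genes of the p53 target and apoptosis list rose in 12 of 21 (2 fell, adjusted p = 0.0316, own-correlation adjusted p = 0.433), Trp73 by 2.42 ± 0.24. The total was 10014 genes, 4722 higher and 5292 lower, 1429 and 1688 at least 2-fold. Adjusted over the list alone, 32 S phase, 25 mitotic, 18 bipolar, 23 rod, 8 cone, 17 progenitor, 15 immediate early, 15 ATF4, 5 lens, 16 Müller glia, 14 neurogenic, 11 E2F family, 8 CDK and 14 p53 genes passed.

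**Figure D3:**
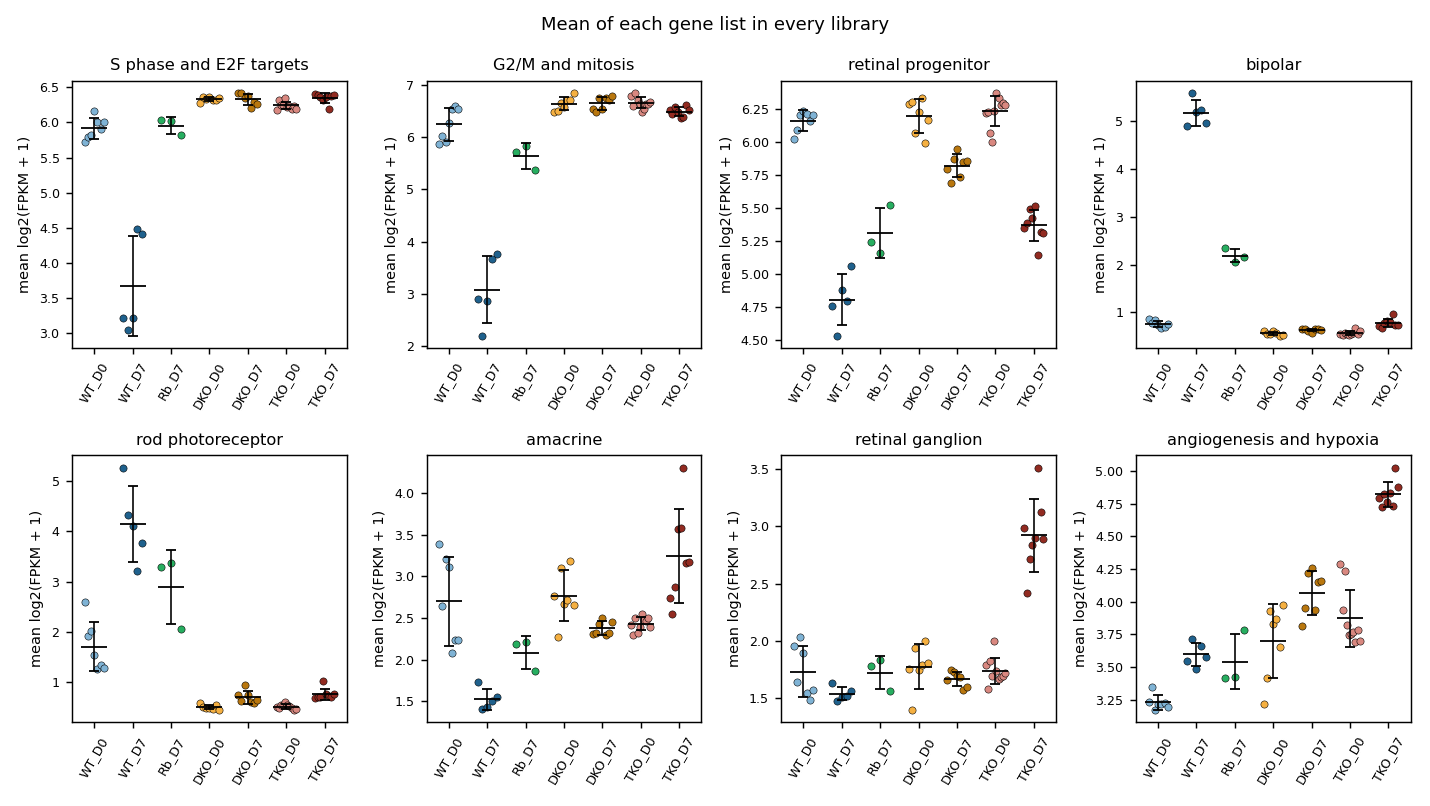
Mean log2(FPKM + 1) of the tested genes of 8 lists by group, with 1 point per library and bars for the mean and SD. The ganglion list lay between 2.42 and 3.51 in TKO_D7 and between 1.57 and 1.75 in DKO_D7, and the bipolar list between 4.91 and 5.59 in WT_D7 and between 2.06 and 2.34 in Rb_D7.

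Set against Rb1 loss alone at D7, the additional loss of Rbl1 came with lower photoreceptor genes and higher mitotic genes. Cone genes fell in 8 of 8 (adjusted p = 3.86e-06, own-correlation adjusted p = 0.0736), Gngt2 by 5.50 ± 0.46 (125 ± 82.2 FPKM in Rb_D7, n = 3, and 1.45 ± 1.1 in DKO_D7, n = 7; adjusted p = 4.4e-13). Rod genes fell in 21 of 23 (adjusted p = 7.29e-11, own-correlation adjusted p = 0.317), Nrl by 4.82 ± 0.43 and Nr2e3 by 4.62 ± 0.49. Bipolar genes fell in 15 of 19 and rose in 2 (adjusted p = 1.77e-11, own-correlation adjusted p = 0.0516), with Lhx4 at -3.47 ± 0.22 and Isl1 at -3.30 ± 0.26. Mitotic genes rose in 24 of 25 (adjusted p = 3.32e-11, own-correlation adjusted p = 0.317), Aurkb and Ttk by 1.29 ± 0.21 and 1.27 ± 0.17. S phase genes rose in 16 of 32 (adjusted p = 0.000618, own-correlation adjusted p = 0.68), Mcm10 by 1.20 ± 0.16. Progenitor genes rose in 13 of 18 (1 fell, adjusted p = 0.00017, own-correlation adjusted p = 0.317), Sfrp2 by 1.42 ± 0.18, Notch1 by 1.03 ± 0.14 and Sox2 by 0.90 ± 0.12. ATF4 targets rose in 13 of 19 (1 fell, adjusted p = 0.00017, own-correlation adjusted p = 0.317), Stc2 by 2.83 ± 0.28 and Asns by 2.40 ± 0.33. Glycolysis genes rose in 10 of 20 (2 fell, adjusted p = 0.0029, own-correlation adjusted p = 0.542), Hk2 by 1.80 ± 0.19. Interferon genes fell in 9 of 15 (1 rose, adjusted p = 0.0029, own-correlation adjusted p = 0.317), Oasl2 by 1.95 ± 0.18 and Irf7 by 1.63 ± 0.16, though not with the filter at 5 FPKM (adjusted p = 0.223). Müller glia genes fell in 10 of 17 (3 rose, adjusted p = 0.00178, own-correlation adjusted p = 0.317), Apoe by 2.26 ± 0.30 and Aqp4 by 1.72 ± 0.11. Neurod4 and Neurod1 fell by 2.33 ± 0.23 and 1.72 ± 0.19. E2F family genes rose in 7 of 11 (1 fell, adjusted p = 0.00519, own-correlation adjusted p = 0.317). Hypoxia genes rose in 10 of 15 (2 fell, adjusted p = 0.0114, own-correlation adjusted p = 0.45), the latter not with the filter at 5 FPKM (adjusted p = 0.0712). Lens genes fell in 4 of 6 (adjusted p = 0.00546, own-correlation adjusted p = 0.23), though not without the filter (adjusted p = 0.0695). In all 6626 genes changed, 2919 higher and 3707 lower, 320 and 715 at least 2-fold. Members past the threshold adjusted over the list alone were 8 cone, 21 rod, 17 bipolar, 25 mitotic, 16 S phase, 15 progenitor, 14 ATF4, 12 glycolysis, 10 interferon, 13 Müller glia, 8 E2F family, 12 hypoxia and 4 lens genes.

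The tumor libraries (TKO_D7) were next set against WT_D7. Cell cycle, hypoxia, ganglion and amacrine genes were higher in them, and bipolar, photoreceptor and Müller glia genes were lower. S phase genes rose in 32 of 32 and mitotic genes in 25 of 25 (adjusted p = 3.25e-19 and 3.15e-18, both own-correlation adjusted p = 0.236), Mki67 by 4.14 ± 0.18 (adjusted p = 4.37e-25). Bipolar genes fell in 19 of 19 (adjusted p = 1.5e-17, own-correlation adjusted p = 0.00594), Grm6 at -7.03 ± 0.08 and Isl1 at -6.61 ± 0.22. Rod genes fell in 23 of 23 and cone genes in 7 of 8 (adjusted p = 9.46e-12 and 0.00507, both own-correlation adjusted p = 0.236). Müller glia genes fell in 12 of 17 (3 rose, adjusted p = 0.00658, own-correlation adjusted p = 0.314), Rlbp1 by 2.46 ± 0.22. Hypoxia genes rose in 12 of 15 (2 fell, adjusted p = 0.00186, own-correlation adjusted p = 0.288), Adm by 4.36 ± 0.27 (0.421 ± 0.353 FPKM in WT_D7, n = 5, and 27.9 ± 5.07 in TKO_D7, n = 8) and Egln3 by 3.13 ± 0.16. Amacrine genes rose in 14 of 16 (2 fell, adjusted p = 0.00186, own-correlation adjusted p = 0.324), Prdm13 by 4.06 ± 0.36 and Tfap2c by 3.53 ± 0.20. Ganglion genes rose in 11 of 13 (2 fell, adjusted p = 0.00186, own-correlation adjusted p = 0.236), Ebf3 by 3.64 ± 0.25 and Stmn2 by 3.11 ± 0.23. Microglia genes rose in 13 of 14 (adjusted p = 0.0168, own-correlation adjusted p = 0.57), Lyz2 by 1.98 ± 0.43. So did 6 of 6 erythroid genes, Hbb-b1 by 3.78 ± 0.74, and 4 of 6 pigment genes, Pmel by 1.19 ± 0.43. The microglia list no longer passed without TKO_D7 4, 5 and 6 or with the filter at 5 FPKM, the compared groups alone or library weights (adjusted p = 0.0511 to 0.143). Without TKO_D7 4, 5 and 6, Lyz2 was at 0.79, Hbb-b1 at 2.12, Rgs5 at 0.64 and Pmel at 0.19 (adjusted p = 0.536). Pmel was at 0.76 without TKO_D7 6. It did not pass without 1048043 or the libraries of several suffixes, with title number as a random block or averaged first, or with the compared groups alone (adjusted p = 0.0518 to 0.232), where Rgs5 did not either (0.0574). For the erythroid and pigment lists the set test gave adjusted p = 0.102 and 0.425. Of the endothelium and pericyte genes 6 of 11 rose and 4 fell (adjusted p = 0.818), Flt1 falling by 1.89 ± 0.15 and Rgs5 rising by 1.41 ± 0.35. The horizontal cell list (1 of 3 risen, 2 fallen) and the astrocyte list (2 of 6 risen, 3 fallen) gave adjusted p = 0.628 and 0.51. ATF4 targets rose in 16 of 19 (2 fell, adjusted p = 0.000341, own-correlation adjusted p = 0.288). Targets of p53 rose in 14 of 21 (1 fell, adjusted p = 0.00186, own-correlation adjusted p = 0.236), Eda2r by 2.24 ± 0.21. CDK inhibitor and D cyclin genes rose in 7 of 9 (2 fell, adjusted p = 0.0196, own-correlation adjusted p = 0.236), Cdkn1a by 3.55 ± 0.24 and Cdkn1c by 2.54 ± 0.18. E2F family genes rose in 10 of 11 (1 fell, adjusted p = 0.00023, own-correlation adjusted p = 0.236). Neurogenic genes rose in 12 of 18 (4 fell, adjusted p = 0.0148, own-correlation adjusted p = 0.314). Progenitor genes rose in 12 of 18 (1 fell, adjusted p = 0.0102, own-correlation adjusted p = 0.324). Crabp1 rose by 5.19 ± 0.31. The total was 10242 genes, 4740 higher and 5502 lower, 1409 and 1492 at least 2-fold. By p-values adjusted over the list alone, 32 S phase, 25 mitotic, 19 bipolar, 23 rod, 15 Müller glia, 14 hypoxia, 16 amacrine, 13 ganglion, 13 microglia, 6 erythroid, 4 pigment, 10 endothelium, 3 horizontal, 5 astrocyte, 18 ATF4, 15 p53, 9 CDK, 8 cone, 11 E2F family, 16 neurogenic and 12 progenitor genes passed.

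Tumor (TKO_D7) and pre-tumorigenic (DKO_D7) cells were compared at D7. Ganglion, amacrine, hypoxia and glycolysis genes were higher in TKO_D7, and progenitor and immediate early genes were lower. Ganglion genes rose in 11 of 13 (adjusted p = 1.68e-09, own-correlation adjusted p = 0.0246), the pan-neuronal Tubb3 by 2.63 ± 0.19 (11.7 ± 3.29 FPKM in DKO_D7, n = 7, and 79.6 ± 28.9 in TKO_D7, n = 8, adjusted p = 1.86e-14), Stmn2 by 2.32 ± 0.20 and Ebf1 by 1.86 ± 0.23. Amacrine genes rose in 13 of 16 (1 fell, adjusted p = 0.000562, own-correlation adjusted p = 0.543), Calb2 by 1.75 ± 0.36, Neurod2 by 1.69 ± 0.18 and Slc6a9 by 1.56 ± 0.27. Hypoxia genes rose in 12 of 15 (adjusted p = 3.46e-06, own-correlation adjusted p = 0.175), Adm by 2.07 ± 0.25 and Egln3 by 1.20 ± 0.14. Glycolysis genes rose in 16 of 20 (adjusted p = 3.8e-06, own-correlation adjusted p = 0.518), Slc2a3 by 1.16 ± 0.18 and Ldha by 0.80 ± 0.15. Progenitor genes fell in 11 of 18 (1 rose, adjusted p = 0.000144, own-correlation adjusted p = 0.403), the Notch effectors Hes5 and Hes1 by 2.13 ± 0.17 and 1.63 ± 0.17. Immediate early genes fell in 14 of 18 (1 rose, adjusted p = 6.79e-05, own-correlation adjusted p = 0.543), Egr1 by 1.92 ± 0.27 and Fos by 1.78 ± 0.28. FOXO targets fell in 9 of 17 and rose in 3 (adjusted p = 0.0154, own-correlation adjusted p = 0.175), Irs2 falling by 0.89 ± 0.13 and Pik3ip1 by 0.88 ± 0.12. Müller glia genes fell in 11 of 17 (3 rose, adjusted p = 0.026, own-correlation adjusted p = 0.58), with Sox9 at -0.82 ± 0.16, while Gfap, a gene of reactive glia, rose by 0.97 ± 0.12. ATF4 targets rose in 9 of 19 (adjusted p = 0.0392, own-correlation adjusted p = 0.595). Ccnd1 fell by 2.13 ± 0.13 and Cdkn1c rose by 1.31 ± 0.16, while 1 of the S phase genes rose and 1 fell and 5 of 25 mitotic genes fell (camera adjusted p = 0.899 and 0.0942). The largest rises were AA465934 (5.11 ± 0.28), Nhlh2 (3.60 ± 0.41), Lcn2 (3.11 ± 0.22) and Igfbpl1 (2.76 ± 0.25), and Cyp26a1 (-2.12 ± 0.15) was among the largest falls. Microglia genes rose in 13 of 14 and erythroid genes in 5 of 6 (adjusted p = 0.000146 and 0.026, both own-correlation adjusted p = 0.58). Pigment genes rose in 5 of 6 (adjusted p = 0.0433, own-correlation adjusted p = 0.592). These lists were highest in TKO_D7 libraries 4, 5 and 6, where C1qa measured 6.42, 12.5 and 15.4 FPKM and Hbb-b1 196, 174 and 282. In all 5813 genes changed, 2967 higher and 2846 lower, 310 and 116 at least 2-fold. When adjusted over the list alone, 12 ganglion, 14 amacrine, 12 hypoxia, 16 glycolysis, 12 progenitor, 17 immediate early, 12 FOXO, 13 microglia, 6 erythroid, 5 pigment, 14 Müller glia and 9 ATF4 genes passed. Without libraries 4, 5 and 6, left out after the data were seen, 4725 genes passed, 4486 of them among the 5813, Calb2 was at 1.08 and Slc6a9 at 0.98. The microglia list no longer passed without TKO_D7 4, 5 and 6 (adjusted p = 0.0671). Calls also ended for the erythroid list without TKO_D7 4 or 6 (adjusted p = 0.0587 to 0.0589) or without TKO_D7 4, 5 and 6 or with the compared groups alone or library weights (0.0902 to 0.604), for the pigment list without DKO_D7 1, 2 or 6 or TKO_D7 4, 5 or 6 (adjusted p = 0.051 to 0.0911) or without the DKO_D7 libraries of 1047823 or TKO_D7 4, 5 and 6, with a pseudocount of 0.1, the filter at 5 FPKM, the compared groups alone, library weights or 1 mean per title number or after median ratio scaling (0.0506 to 0.574), for the Müller glia list without DKO_D7 1 (adjusted p = 0.051) or without the DKO_D7 libraries of 1047823 or TKO_D7 4, 5 and 6 or with 1 mean per title number (0.0559 to 0.0793) and for the ATF4 list without DKO_D7 1, 2 or 5 or TKO_D7 3, 4 or 5 (adjusted p = 0.0537 to 0.0717) or without the DKO_D7 libraries of 1047823 or TKO_D7 4, 5 and 6 or with 1 mean per title number (0.0671 to 0.111). With each title number averaged first Calb2 and Ldha did not pass (adjusted p = 0.0503 and 0.0619).

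**Figure D4:**
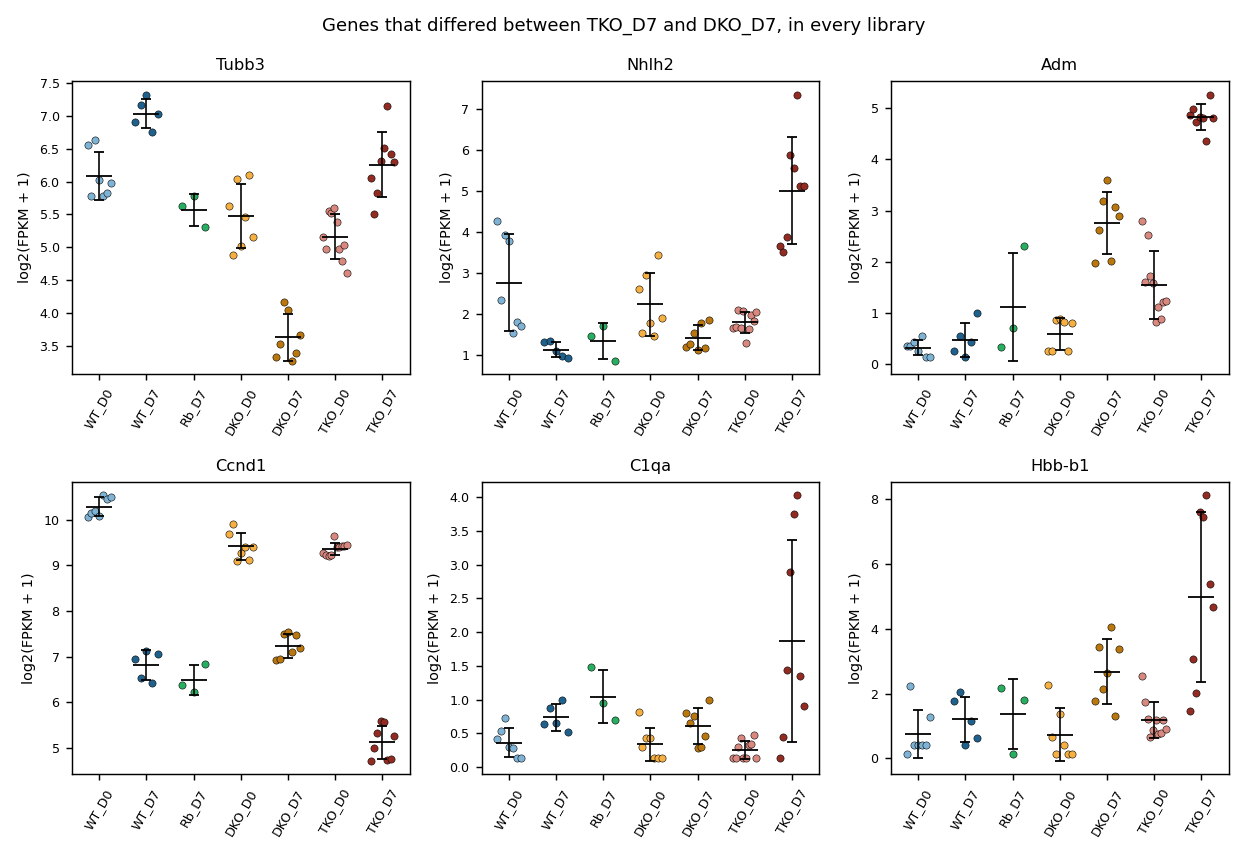
log2(FPKM + 1) of 6 genes by group, with 1 point per library and bars for the mean and SD. Tubb3 measured 44.4 to 140.3 FPKM in TKO_D7 and 8.71 to 17.1 in DKO_D7, and Ccnd1 25.1 to 46.9 in TKO_D7 and 121 to 186 in DKO_D7.

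The change from D0 to D7 was measured within each genotype. In the wild type, genes of bipolar cells, rods and Müller glia rose and cell cycle, progenitor and sterol genes fell. Bipolar genes rose in 19 of 19 (adjusted p = 8.75e-20, own-correlation adjusted p = 0.00226), Isl1 by 7.32 ± 0.22, Grm6 by 6.94 ± 0.08 and Pcp2 by 6.39 ± 0.22, with Pcp4 at 7.59 ± 0.27 and Vsx2 at 1.99 ± 0.11. Rod genes rose in 23 of 23 (adjusted p = 7.53e-10, own-correlation adjusted p = 0.304), Rho by 4.45 ± 0.17. Müller glia genes rose in 11 of 17 (3 fell, adjusted p = 0.0146, own-correlation adjusted p = 0.508), Rlbp1 by 3.24 ± 0.22 and Apoe by 2.95 ± 0.26. S phase genes fell in 32 of 32 (adjusted p = 2.58e-18, own-correlation adjusted p = 0.209). Mitotic genes fell in 25 of 25 (adjusted p = 6.03e-19, own-correlation adjusted p = 0.199), Mki67 by 3.60 ± 0.18 (151 ± 21.7 FPKM in WT_D0, n = 7, and 12.9 ± 7.01 in WT_D7, n = 5; adjusted p = 2.35e-22), and Ccnd1 fell by 3.47 ± 0.15. Progenitor genes fell in 17 of 18 (1 rose, adjusted p = 8.43e-07, own-correlation adjusted p = 0.199), Fgf15 by 4.92 ± 0.20 and Foxn4 by 3.68 ± 0.20. Neurogenic genes fell in 13 of 18 (4 rose, adjusted p = 0.00407, own-correlation adjusted p = 0.304), Atoh7 by 3.25 ± 0.31. Sterol genes fell in 18 of 25 (2 rose, adjusted p = 3.25e-05, own-correlation adjusted p = 0.46), Ldlr by 3.56 ± 0.21. Glycolysis genes rose in 17 of 20 (3 fell, adjusted p = 0.0023, own-correlation adjusted p = 0.546), Aldoc by 4.91 ± 0.17. E2F family genes fell in 10 of 11 (1 rose, adjusted p = 3.64e-05, own-correlation adjusted p = 0.199). Amacrine genes fell in 10 of 16 (2 rose, adjusted p = 0.0293, own-correlation adjusted p = 0.649). Lens genes rose in 5 of 6 (adjusted p = 0.0146, own-correlation adjusted p = 0.209). Aldh1a3 (-4.31 ± 0.16) and Gli1 (-4.36 ± 0.22) were among the largest falls. The total was 9387 genes, 4834 higher and 4553 lower at D7, 1459 and 1160 at least 2-fold. Adjusted over the list alone, 19 bipolar, 23 rod, 14 Müller glia, 32 S phase, 25 mitotic, 18 progenitor, 17 neurogenic, 20 sterol, 20 glycolysis, 11 E2F family, 12 amacrine and 5 lens genes passed. The amacrine list no longer passed without WT_D0 1 (adjusted p = 0.0514) or without 1032030, 1048043 or the libraries of several suffixes or with library weights (0.0534 to 0.198), nor the lens list without the filter (adjusted p = 0.0995).

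In DKO cells 3574 genes changed from D0 to D7, 1798 higher and 1776 lower (190 and 84 at least 2-fold). Sterol genes fell, immediate early and Müller glia genes rose, while 1 of the S phase genes rose and 1 fell and the mitotic genes had a median change of 0.02 (camera adjusted p = 0.867 and 0.96). Sterol genes fell in 22 of 25 (adjusted p = 9.79e-18, own-correlation adjusted p = 0.205), Ldlr by 2.14 ± 0.19 (16.3 ± 9.34 FPKM in DKO_D0, n = 7, and 2.64 ± 0.918 in DKO_D7, n = 7; adjusted p = 4.02e-12) and Dhcr24 by 1.83 ± 0.17. Müller glia genes rose in 11 of 17 (2 fell, adjusted p = 0.000319, own-correlation adjusted p = 0.477), Rlbp1 by 2.03 ± 0.20 and Apoe by 1.67 ± 0.23. Immediate early genes rose in 10 of 18 (adjusted p = 0.000193, own-correlation adjusted p = 0.652), Nr4a1 by 1.67 ± 0.28 and Zfp36 by 1.58 ± 0.22. Interferon genes rose in 7 of 15 (adjusted p = 0.00131, own-correlation adjusted p = 0.477), B2m by 1.06 ± 0.15. Of the glycolysis genes 5 of 20 (1 fell) rose (adjusted p = 0.00995, own-correlation adjusted p = 0.941). Hypoxia genes rose in 6 of 15 (1 fell, adjusted p = 0.0371, own-correlation adjusted p = 0.784). CDK inhibitor and D cyclin genes rose in 5 of 9 (1 fell, adjusted p = 0.0498, own-correlation adjusted p = 0.477). Progenitor genes fell in 9 of 18 (1 rose, adjusted p = 0.00102, own-correlation adjusted p = 0.477), Fgf15 by 3.07 ± 0.19 and Six6 by 0.65 ± 0.09. Ccnd1 fell by 2.18 ± 0.14, and Cdkn1c and Cdkn2a rose by 1.73 ± 0.16 and 1.34 ± 0.17. Mapt (2.86 ± 0.15) and Mt2 (2.50 ± 0.35) were among the largest rises. Bipolar genes passed in 3 members upward and 1 downward (adjusted p = 0.665). Members past the threshold adjusted over the list alone were 24 sterol, 13 Müller glia, 10 immediate early, 8 interferon, 6 glycolysis, 9 hypoxia, 7 CDK and 10 progenitor genes. Calls ended for the glycolysis list without DKO_D0 1 or 2 (adjusted p = 0.08 to 0.145) or without 1032037 or the libraries of several suffixes or with library weights or title number as a fixed term (0.159 to 0.691), for the hypoxia list without DKO_D0 1, 2 or 6 or DKO_D7 3, 4, 6 or 7 (adjusted p = 0.0549 to 0.145) or without 1032037 or the libraries of several suffixes or with the compared groups alone or title number as a fixed term (0.0772 to 0.723) and for the CDK list without DKO_D0 2, 3, 4, 5, 6 or 7 or DKO_D7 1, 3, 4, 6 or 7 (adjusted p = 0.0505 to 0.0715) or without the DKO_D7 libraries of 1047823, with a pseudocount of 0.1, the filter at 5 FPKM or 1 mean per title number or after median ratio scaling (0.0561 to 0.102). Title number 1047823 holds libraries of both stages, and with title number as a fixed term 3633 genes passed, 2450 of them among the 3574. This term also turned the medians of the glycolysis and hypoxia lists from 0.24 and 0.32 to -0.04 and -0.02 and put Apoe at 2.88.

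In TKO cells 7845 genes changed from D0 to D7, 4029 higher and 3816 lower (551 and 210 at least 2-fold). Sterol and progenitor genes fell, and hypoxia, ganglion, interferon and glycolysis genes rose. Sterol genes fell in 23 of 25 (adjusted p = 4.83e-14, own-correlation adjusted p = 0.151), Ldlr at -2.77 ± 0.17 and Scd1 at -1.77 ± 0.11. Progenitor genes fell in 13 of 18 (1 rose, adjusted p = 1.99e-07, own-correlation adjusted p = 0.151), Fgf15 by 3.75 ± 0.17 and Sfrp2 by 1.75 ± 0.12. Hypoxia genes rose in 13 of 15 (adjusted p = 5.93e-06, own-correlation adjusted p = 0.161), Adm by 3.29 ± 0.23 (2.24 ± 1.73 FPKM in TKO_D0, n = 10, and 27.9 ± 5.07 in TKO_D7, n = 8; adjusted p = 1.41e-16) and Vegfa by 1.31 ± 0.14. Ganglion genes rose in 11 of 13 (1 fell, adjusted p = 6.04e-06, own-correlation adjusted p = 0.151), Ebf3 by 2.79 ± 0.21 and Gap43 by 2.22 ± 0.15. Amacrine genes rose in 10 of 16 (1 fell, adjusted p = 0.00763, own-correlation adjusted p = 0.553), Neurod2 by 2.75 ± 0.16. Interferon genes rose in 12 of 15 (adjusted p = 0.000199, own-correlation adjusted p = 0.264), B2m by 1.86 ± 0.14 and H2-D1 by 1.47 ± 0.13. Of the glycolysis genes 16 of 20 (2 fell) rose (adjusted p = 0.00277, own-correlation adjusted p = 0.553). Microglia genes rose in 14 of 14 (adjusted p = 0.000199, own-correlation adjusted p = 0.553), C1qb by 1.76 ± 0.31. Erythroid and pigment genes each rose in 6 of 6 (adjusted p = 0.0155, own-correlation adjusted p = 0.553), pigment genes again with TKO_D7 4, 5 and 6 the highest. Ccnd1 fell by 4.26 ± 0.12, Cdkn1c rose by 2.60 ± 0.15 and Cdkn1a by 1.35 ± 0.20. Mapt (3.61 ± 0.14) and Lcn2 (3.27 ± 0.20) were among the largest rises. Without TKO_D7 4, 5 and 6 the count was 6897, 6630 of them among the 7845, and C1qb was at 0.77. Calls ended for the amacrine list without TKO_D7 4, 5 and 6 or with 1084380 alone (adjusted p = 0.0742 to 0.083), for the erythroid list without TKO_D7 4, 5 and 6 or with 1084380 alone or library weights (adjusted p = 0.0585 to 0.188) and for the pigment list without TKO_D7 4, 5 and 6 or with 1084380 alone or the filter at 5 FPKM (adjusted p = 0.0901 to 0.203). By p-values adjusted over the list alone, 24 sterol, 14 progenitor, 13 hypoxia, 12 ganglion, 11 amacrine, 12 interferon, 18 glycolysis, 14 microglia, 6 erythroid and 6 pigment genes passed.

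Interaction terms tested whether the change from D0 to D7 differed between genotypes. Compared with WT, bipolar and rod genes changed more negatively in DKO and TKO, and cell cycle, progenitor and neurogenic genes more positively. Between DKO and WT the change differed for 7866 genes, 3822 more positive and 4044 more negative in DKO. Bipolar genes changed more negatively in 19 of 19 (adjusted p = 4.73e-25, own-correlation adjusted p = 0.000394), with Isl1 at -7.44 ± 0.30 and Grm6 at -6.93 ± 0.11. Rod genes did so in 23 of 23 (adjusted p = 9.13e-10, own-correlation adjusted p = 0.251). Glycolysis genes did so in 13 of 20 (2 the other way, adjusted p = 0.0264, own-correlation adjusted p = 0.712). Lens genes did so in 5 of 6 (adjusted p = 0.0241, own-correlation adjusted p = 0.177). S phase and mitotic genes changed more positively in 32 of 32 and 25 of 25 (adjusted p = 7.51e-21 and 1.3e-22, both own-correlation adjusted p = 0.177), with Mki67 at 3.65 ± 0.24 and E2f8 at 3.62 ± 0.20. So did E2F family genes in 10 of 11 (1 the other way, adjusted p = 3.48e-05, own-correlation adjusted p = 0.177) and progenitor genes in 15 of 18 (1 the other way, adjusted p = 4.66e-05, own-correlation adjusted p = 0.177). The same held for neurogenic genes in 12 of 18 (3 the other way, adjusted p = 0.000615, own-correlation adjusted p = 0.177), immediate early genes in 10 of 18 (adjusted p = 0.00952, own-correlation adjusted p = 0.712) and CDK inhibitor and D cyclin genes in 6 of 9 (adjusted p = 0.017, own-correlation adjusted p = 0.177). Adjusted over the list alone, 19 bipolar, 23 rod, 16 glycolysis, 5 lens, 32 S phase, 25 mitotic, 11 E2F family, 16 progenitor, 16 neurogenic, 10 immediate early and 6 CDK genes passed. Calls ended for the lens list without the filter, with a pseudocount of 0.1 or after quantile normalization (adjusted p = 0.0544 to 0.0838) and for the glycolysis list with the compared groups alone or 1 mean per title number (adjusted p = 0.0544 to 0.214).

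Between TKO and WT the change differed for 8098 genes, 3884 more positive and 4214 more negative in TKO. The bipolar list was lower in 19 of 19 (adjusted p = 6.37e-26, own-correlation adjusted p = 0.000299), the rod list in 21 of 23 (adjusted p = 4.45e-10, own-correlation adjusted p = 0.236). So were the Müller glia list in 11 of 17 (1 the other way, adjusted p = 0.00493, own-correlation adjusted p = 0.37) and the lens list in 5 of 6 (adjusted p = 0.0234, own-correlation adjusted p = 0.202). More positive changes were found in 32 of 32 (adjusted p = 2.61e-23, own-correlation adjusted p = 0.164) S phase genes, 25 of 25 (adjusted p = 6.14e-23, own-correlation adjusted p = 0.156) mitotic genes and 10 of 11 (1 the other way, adjusted p = 0.00015, own-correlation adjusted p = 0.202) E2F family genes. They were also found in 14 of 18 (adjusted p = 1.72e-05, own-correlation adjusted p = 0.156) neurogenic genes and 11 of 18 (1 the other way, adjusted p = 0.0187, own-correlation adjusted p = 0.467) progenitor genes, and in 13 of 16 (1 the other way, adjusted p = 5.04e-05, own-correlation adjusted p = 0.285) amacrine genes and 9 of 13 (adjusted p = 0.000666, own-correlation adjusted p = 0.202) ganglion cell genes. CDK inhibitor and D cyclin genes changed more positively in 6 of 9 (1 the other way, adjusted p = 0.0211, own-correlation adjusted p = 0.202). Microglia genes did so in 12 of 14 (adjusted p = 0.0211, own-correlation adjusted p = 0.634). The differences for Crabp1 and Nhlh2 were 5.41 ± 0.41 and 4.86 ± 0.59. Members past the threshold adjusted over the list alone were 19 bipolar, 21 rod, 12 Müller glia, 5 lens, 32 S phase, 25 mitotic, 11 E2F family, 14 neurogenic, 12 progenitor, 14 amacrine, 9 ganglion, 7 CDK and 12 microglia genes. Calls ended for the microglia list without 1048043, the libraries of several suffixes or TKO_D7 4, 5 and 6 or with 1084380 alone, the filter at 5 FPKM or library weights (adjusted p = 0.0508 to 0.188), for the progenitor list with 1084380 alone (adjusted p = 0.0887) and for the lens list with 1084380 alone or a pseudocount of 0.1 (adjusted p = 0.0506 to 0.0804).

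Between TKO and DKO the change from D0 to D7 differed for 3403 genes, 1819 more positive and 1584 more negative in TKO. Ganglion genes changed more positively in 10 of 13 (1 the other way, adjusted p = 6.15e-10, own-correlation adjusted p = 0.0194). Amacrine genes did so in 12 of 16 (1 the other way, adjusted p = 4.9e-06, own-correlation adjusted p = 0.416). Hypoxia genes did so in 10 of 15 (adjusted p = 8.42e-05, own-correlation adjusted p = 0.412). Progenitor genes changed more negatively in 11 of 18 (adjusted p = 1.13e-05, own-correlation adjusted p = 0.412). So did 6 of 25 sterol genes, 7 of 17 (2 the other way) Müller glia genes and 4 of 18 (1 the other way) immediate early genes (each list adjusted p = 0.0137, own-correlation adjusted p = 0.678). The differences were 4.05 ± 0.56 for Nhlh2 (adjusted p = 9.74e-07), 3.13 ± 0.34 for Igfbpl1, 3.11 ± 0.30 for Lcn2 and -2.08 ± 0.19 for Ccnd1. Microglia and pigment genes changed more positively in 10 of 14 and 4 of 6 (adjusted p = 0.000272 and 0.0108, both own-correlation adjusted p = 0.678). When adjusted over the list alone, 11 ganglion, 13 amacrine, 10 hypoxia, 11 progenitor, 6 sterol, 12 Müller glia, 10 immediate early, 12 microglia and 6 pigment genes passed. Calls ended for the microglia list without TKO_D7 4, 5 and 6 or with the filter at 5 FPKM (adjusted p = 0.0536 to 0.062) and for the pigment list without TKO_D7 4, 5 and 6 or with 1084380 alone, the filter at 5 FPKM or library weights (adjusted p = 0.0641 to 0.198). The sterol list no longer passed with 1084380 alone (adjusted p = 0.196), nor the Müller glia list without TKO_D7 4, 5 and 6 or with 1084380 alone (adjusted p = 0.0573 to 0.196). Nor did the immediate early list without TKO_D7 2 (adjusted p = 0.055) or with 1084380 alone, the filter at 5 FPKM or library weights (0.0575 to 0.0852). With 1084380 alone 5500 genes passed, and with library weights 5127.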

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

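The tests of the 3 patterns below were chosen after the results were seen, except the count of genes near Pten and the regrouping of single libraries.

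Within groups of 4 to 10 libraries, 22 values in 14 libraries stood apart from the others of their group, among 392 sets of values tested, where chance gives about 1 in 20. In the library labelled wild type, WT_D0 4, these were Rbl1 (0.487 FPKM), E2f2 (33.5), Slc2a3 (3.32), Slc7a5 (62.9) and Trp73 (2.49). Others were Grm6 in WT_D0 7 (0.355), Cdkn1a and Pmel in WT_D7 2 (3.39 and 2.4), Cdkn2a in DKO_D0 2 (0.4), Junb in DKO_D0 7 (20.7), Grm6, Pcp2 and Rlbp1 in DKO_D7 1 (0.268, 0.461 and 116), Nrl in DKO_D7 3 (2.28) and Lcn2 in DKO_D7 7 (0.612). In the TKO groups they were Asns and Neurod4 in TKO_D0 2 (98.8 and 26.1), B2m in TKO_D0 3 (37.8), Flt1 in TKO_D7 1 (1.11), Fos in TKO_D7 2 (164), B2m in TKO_D7 3 (142) and Irs2 in TKO_D7 5 (9.11).

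The first pattern is Rbl1 at the level of the mutants in the library labelled wild type. On a scale from the other WT_D0 libraries (0) to DKO_D0 (1), over the 4889 genes that separate them, this library lay at 0.36, the other WT_D0 libraries between -0.22 and 0.18 and DKO_D0 between 0.9 and 1.12. This argues against a DKO or TKO retina under a wild type label. A failed estimate of Rbl1 cannot be told apart, since 0.487 lies above 0 but can be wrong. It would leave E2f2, Slc2a3, Slc7a5 and Trp73 unexplained, which stood apart toward DKO_D0, but these are 4 of the 22 values above. Over the other genes of the scale the library lay at 0.35, a gap of 0.296 of the range from the next, too small to stand apart. An animal without Rbl1 and with Rb1 intact stays open too. It cannot be told apart from other differences of 1 library, at 0.18 beyond the next. WT_D0 1 and 2 (20.01 and 18.3 FPKM) were also below the rest (35.9 to 43.7), for a cause not tested.

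By limma's interaction test the D0 to D7 change differed for 7866 genes (DKO against WT), 8098 (TKO against WT) and 3403 (TKO against DKO). Between DKO and WT the differences were 3.62 for E2f8, 3.65 for Mki67, -6.93 for Grm6, -7.44 for Isl1, -0.29 for Pten, 0.27 for Rb1 and 1.44 for Rbl1. Between TKO and WT they were 5.41 for Crabp1, 4.86 for Nhlh2, -0.38 for Pten, 0.75 for Rb1 and 1.32 for Rbl1. Against WT, Rbl1 in DKO and TKO was at 2.44 and 2.3 without the libraries of several suffixes, WT_D0 4 among them, and at 2.49 and 2.37 without 1032030, and Pten between TKO and WT at -0.194 without 1084380. With title number as a random block the calls of Rb1 and Rbl1 between DKO and WT and of Rbl1 and Pten between TKO and WT ended (adjusted p = 0.0658 to 0.199). Between TKO and DKO the differences were -2.08 for Ccnd1, 3.13 for Igfbpl1, 3.11 for Lcn2, 4.05 for Nhlh2 and 0.48 for Rb1. In the library with conflicting stage labels, Rb1 (50.3 FPKM), Mki67 (231) and Trp73 (11.5) lay above every wild type library.

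The second pattern is the rise of 24 ganglion and amacrine genes from DKO_D7 to TKO_D7, with a median of 1.27. RNA from microglia, blood and pigment cells is excluded as the whole source for ganglion but not for amacrine genes. In TKO_D7 1 and 2, where its markers were not above DKO_D7, 18 of the 24 lay above every DKO_D7 library. Ganglion genes averaged 2.979 and 2.42 there and amacrine genes 2.742 and 2.543 (log2, at most 1.748 and 2.504 in DKO_D7). A first version of this test missed its bound, with 19 of the 24 (median 0.98) passing without TKO_D7 4, 5 and 6. Of 23 risen genes of those cells 5 passed. Unsorted cells of the D7 retina are excluded as well, since 32 rod and bipolar genes changed by a median of -0.03% of their WT_D7 level (quartiles -0.32 and 0.45%). TKO_D7 1 and 2 form title number 1048010, so the same 18 genes, no second evidence, argue against a difference between title numbers of TKO_D7. TKO_D7 and DKO_D7 share no title number, so batch and genotype cannot be told apart. A biological difference remains a hypothesis.

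The third pattern is a set of 116 genes that differed the same way between TKO and DKO at both stages by at least 0.6, 54 higher and 62 lower. Strain variants carried along with the Pten allele are excluded as the source of the set, with 1 of 108 located genes within 10 Mb of Pten against a mean of 0.85 in 10000 random sets (p = 0.6). Strain variants in other blocks of the genome cannot be told apart from chance, with 25 genes within 1 Mb of another against a mean of 17.26 (p = 0.09). This case is left open only because the bound for exclusion was moved to that mean after the count was seen. Loss of Pten acting through FOXO targets and glycolysis genes cannot be told apart, as the 5 located members of those lists in the set restate that both lists passed in TKO_D0 against DKO_D0. TKO and DKO share no title number at either stage, so batch differences stay open here as well.

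Regrouping single libraries, taken as exchangeable, excluded a chance placing of them for all 14 counts, but not chance between title numbers (below), with 100 splits each and 56 for Rb_D7 against WT_D7. In 12 contrasts 1 split, the real one, gave as many genes. The highest other counts were 3015 and 3114 for DKO_D0 and TKO_D0 against WT_D0 (4806 and 7099), 4216, 8431 and 8643 for Rb_D7, DKO_D7 and TKO_D7 against WT_D7 (6444, 10014 and 10242). They were 2652 for DKO_D7 against Rb_D7 (6626), 3307 for TKO_D7 against DKO_D7 (5813), 7678, 1709 and 5189 for the stages of WT, DKO and TKO (9387, 3574 and 7845), and 6218 and 1829 for the interactions of TKO with WT and DKO (8098 and 3403). For TKO_D0 against DKO_D0 2 splits gave at least 2988 genes, and the other, with 3115, set the 5 libraries of title number 1084380 with 2 more against the rest. It thus follows that title number, without which the real count was 2343. For the interaction of DKO and WT 2 splits gave at least 7866 genes, and the other, with 9348, kept the D7 libraries in place and exchanged 10 D0 libraries between the genotypes. As title numbers make libraries not fully exchangeable, whole title numbers, 1 to 4 per group, were moved too, a test chosen after the data were seen. For 2 groups this gives 3 to 15 splits, too few for a share under 0.05. The highest other counts were 1135, 6339 and 3757 for DKO_D0 against WT_D0, TKO_D0 against WT_D0 and TKO_D0 against DKO_D0, 4216, 8677 and 1099 for Rb_D7, DKO_D7 and TKO_D7 against WT_D7, 396 and 4070 for DKO_D7 against Rb_D7 and TKO_D7 against DKO_D7, and 39, 2370 and 7230 for the stages of WT, DKO and TKO. For TKO_D0 against DKO_D0 6 of 15 gave at least 2988. For the interactions of DKO with WT, TKO with WT and TKO with DKO 8 of 60, 26 of 90 and 18 of 100 splits gave as many (highest others 9854, 10394 and 5819), though splits that exchange the genotypes at a single stage carry their difference into the interaction. Chance between title numbers therefore stays open for all 14 counts.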

How the results depend on the processing

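Leaving out a title number or TKO_D7 4, 5 and 6 was chosen after the data were seen, and the other alternatives before. Counts of changed genes stayed within 1.5 times with any single library left out, with the pseudocount of 0.1, without the filter or with it at 5 FPKM, after both scalings and without the libraries of several suffixes. With the compared groups alone TKO_D0 against DKO_D0 gave 1937 genes (2988 with all groups) and 8 lists instead of 5. Library weights gave 5127 for the interaction of TKO and DKO (3403). With 1 mean per title number, which leaves fewer samples, the counts were 515, 2691 and 134 for DKO_D0 against WT_D0, TKO_D0 against WT_D0 and TKO_D0 against DKO_D0 (9 lists), and 3597 for Rb_D7 against WT_D7. They were 3372 and 1927 for DKO_D7 against Rb_D7 and TKO_D7 against DKO_D7, 1254 and 3584 for the stages of DKO and TKO, and 5155, 4927 and 350 for the interactions of DKO with WT, TKO with WT and TKO with DKO. Without the WT_D0 libraries of title number 1032030, DKO_D0 against WT_D0 gave 2883 genes. With title number 1084380 alone for TKO_D0, TKO_D0 against DKO_D0 gave 4988 genes and 2 lists, and the interaction of TKO and DKO 5500 genes and 5 of 9 lists. Without title number 1084380 TKO_D0 against DKO_D0 gave 9 lists, and without TKO_D7 4, 5 and 6 TKO_D7 against DKO_D7 gave 7 of 12. Lists past the threshold with any single library left out numbered 3 to 7 for TKO_D0 against DKO_D0, with 3 without DKO_D0 3 or TKO_D0 4. They numbered 5 to 8 for the stages of DKO, with 5 without DKO_D0 2. With the correlation estimated, 11 of 157 list calls held, 1 in each of 11 contrasts. For DKO_D7 against Rb_D7 and the stages of DKO and TKO camera then gave 0 lists, with 3, 1 and 5 at an unadjusted p under 0.05. Apart from fewer samples or genes the causes were not tested.

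Deviations from the group means gave no sign that title number 1047823 pairs DKO_D0 and DKO_D7 libraries (mean correlation 0.003 in 10 pairs, -0.001 in the 39 others). Within groups, where centring makes correlations negative, libraries of 1 title number were more alike (-0.051 in 60 pairs) than others (-0.227 in 89). With title number as a random block (correlation 0.369), DKO_D0 against WT_D0, TKO_D0 against WT_D0 and TKO_D0 against DKO_D0 gave 2327, 3952 and 661 genes. TKO_D7 against DKO_D7 gave 2851, the stages of TKO 4466 and the interaction of TKO and DKO 1088, and the other 8 counts stayed within 1.5 times. Set tests were not run with this block, which camera would have ignored. With title number as a fixed block, Nrl in Rb_D7 against WT_D7 was at -0.052 and the median of the hypoxia list in the stages of DKO at -0.021.

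Of 302 results for named genes, calls were lost for 45 with 1 mean per title number, 18 with the random block and 10 with the compared groups alone, and for at most 5 under any other alternative. Leaving out single libraries gave 4415 results, of which 33 lost their call. In the interactions the calls of Rb1, Rbl1 and Pten between DKO and WT, of Rbl1 and Pten between TKO and WT and of Rb1 between TKO and DKO ended with 1 mean per title number (adjusted p = 0.0504 to 0.257), and 4 of them with the random block too (0.0658 to 0.199). Rb1 between DKO and WT did not pass either without WT_D0 1 or 4, WT_D7 1, 2, 3 or 5, DKO_D0 1, 2 or 5 or DKO_D7 3, 5 or 6 (0.0511 to 0.103), nor Rbl1 between TKO and WT without WT_D0 3, 5, 6 or 7 or WT_D7 2 or 3 (0.0524 to 0.0599). Of 157 list calls, 16 of 49 were lost with title number 1084380 alone, 13 of 60 without TKO_D7 4, 5 and 6, 11 with library weights and 11 of 152 with the filter at 5 FPKM. Of the signs that changed, 3 belonged to called results, the medians of the hypoxia list (above, 0.323 as reported) and the glycolysis list (-0.042 with the fixed block and -0.041 without 1032037, 0.242 as reported) in the stages of DKO and Pten in the stages of TKO, at 0.026 without 1084380 (-0.159 as reported). The others belonged to results without a call. Pten in TKO_D0 against DKO_D0 was at 0.001 after quantile normalization, 0.046 with library weights and 0.152 with title number 1084380 alone (adjusted p = 0.045), and at -0.218 without it (0.0057). In the interaction of TKO and DKO Pten was at 0.012 with the random block, 0.038 with 1 mean per title number and 0.095 without 1084380. In DKO_D7 against WT_D7 it was at 0.003 without the DKO_D7 libraries of 1047823. Quantile normalization put Rbl1 at -0.079 in TKO_D7 against DKO_D7 and at -0.054 in the stages of TKO. Nrl in Rb_D7 against WT_D7 was at -0.052 without the libraries of several suffixes, with the shared title number alone and without 1048043. Without 1048043 Rb1 in the stages of WT was at -0.033, and its range with single libraries left out was -0.017 (WT_D7 4) to 0.09. Pdk1 in TKO_D0 against DKO_D0 was at -0.042 with library weights, -0.056 without the libraries of several suffixes and -0.266 without 1032037, and between -0.056 (without DKO_D0 1) and 0.255 with single libraries left out. The alternative for counts was not run on FPKM.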

Other observations

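The library with conflicting stage labels carried the DKO genotype. It measured 0.553 FPKM for Rbl1, 30.9 for Pten, 559 for Ccnd1 and 1.28 for Nrl. Ccnd1 ran from 544 to 958 in DKO_D0 and from 121 to 186 in DKO_D7.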
